A study of Mus musculus with 6 samples.

How the data were processed

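RNA from the mouse hepatocyte line AML12 was measured in 6 libraries, 3 labelled control and 3 labelled heparin, with the group and replicate number of each library taken from its title. Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was captured with oligo(dT) beads, and libraries were amplified by PCR and sequenced as paired ends on an Illumina NovaSeq. Whether the libraries kept strand information is not given in the sources used here. Poly(A) capture leaves out most RNA without a tail, and it makes values for short-tailed or degraded RNA depend on RNA quality.

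The authors deposited 1 table of raw read counts per gene and library, with Ensembl gene identifiers. The submitters' processing notes name fastp, HISAT2, SAMtools, featureCounts and Subread, and the genome build GRCm39. Their versions, the gene annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Without those settings, reads of gene families, near-identical copies, overlapping genes and antisense genes cannot be assigned with certainty, and such genes are named as uncertain. The header of the deposited table is 1 name shorter than its rows. The names were taken to follow the gene identifier, so the first value per gene is its length and the other 6 are counts; this length equals the merged exon length in GENCODE M21 for 44365 of 49326 shared genes (exact equality). All sample columns were used.

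Gene symbols came from the GENCODE M21 name table (build GRCm38), which matched 49326 of 49671 identifiers. The 345 without a symbol held 0.0845% of the counts. Because that build differs from the one in the submitters' notes, no coordinates are given, and the annotation served only for symbols, chromosome membership and GC content. Of the listed genes, 17 were matched through RefSeq synonyms, and 4 had no match.

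Of the genes in the table, 23321 had a count, and filterByExpr with its default settings kept 14061. Library sizes were scaled by TMM. Each gene was tested between the groups with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) in R 4.3.3, on all 6 libraries with group as the 1 term, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with 0.05 as the threshold and no minimum fold. Fold changes are heparin over control, as fitted by edgeR with its small prior count, so those of genes with very few reads depend on it. Standard errors were taken as the absolute log2 fold change divided by the square root of the F statistic. CPM values are TMM-scaled and given as mean ± SD of 3 libraries.

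Library totals ranged from 32282319 to 44642664 counts. A count of 0 was read as allowing up to 3 counts of the library's total. These limits cover counting error only, since the labels name PCR and no molecular identifiers, and PCR copies are not independent molecules. Replicates of a group differed by more than sampling noise. Over 14029 genes the chi-square per gene between 2 libraries of a group lay between 8.35 and 81.6, where about 1 is expected from counting alone. It scaled libraries by their totals and not by TMM, so a shift in the make-up of a library also raises it.

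Before the data were examined, 32 gene lists were fixed, covering FGF and ERK signalling, coagulation, heparan sulfate, liver function, lipid metabolism, inflammation, matrix, stress, the cell cycle, other liver cell types and RNA quality. Lists with at least 5 measured members were tested against all other genes with camera of limma 3.58.1, two-sided, on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 30 lists tested. Camera with a correlation estimated from the libraries, and fry, were run as alternatives. With an estimated correlation, camera also takes its degrees of freedom from the 6 libraries rather than from the genes. Fry does not compare a list with other genes. Members of several lists count in each.

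The rule for named genes was also fixed before the data were examined. It took the 10 rises and 10 falls with the largest absolute log2 fold change among genes with adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the groups; Hrg, Fgfr1, Fgfr2, Fgfr3, Fgfr4 and Klb; and, for each list described, up to 4 measured members with the smallest p. Some genes that the rule names are not reported here. Genes outside the rule are said to have been named after their values were seen.

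The test was checked on simulated counts for the comparison of heparin with control, drawn for the 14061 genes from the real means, library sizes and dispersions, with 200 genes changed. It recovered 56.7% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 98.5% of those changed 4-fold, and 7.14% of its calls were genes left unchanged. In a second simulation, the 1 shifted list was called and 0 of 29 unchanged lists were. Both simulations drew each gene independently, so they do not test list calls where members are correlated. In the data that correlation was estimated at 0.419 for DNA replication and 0.543 for cholesterol genes. The genes changed in the first simulation were also far fewer than the 5705 called in the data.

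Alternatives fixed with the design were RLE size factors, no scaling beyond library size, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom, each library left out in turn, the replicate number as a block, and an absolute log2 fold change of at least 1. Taking out each library's trend with gene length and GC content (known for 99.8% of the genes tested), and leaving out mitochondrial transcripts, were added after the data were seen. Plots were drawn with matplotlib 3.10.9.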

Results

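Poly(A) RNA was sequenced from AML12 cells, a non-tumour mouse hepatocyte line derived from a mouse carrying a TGF-alpha transgene. The labels gave 6 libraries, 3 from control cells and 3 from cells exposed to heparin, a sulfated polysaccharide used as an anticoagulant. Dose and duration of the heparin exposure are not given in the sources used here. The counts assigned to genes totalled 38177002, 35703984 and 32282319 in controls 1, 2 and 3, and 34389814, 34484560 and 44642664 in heparin 1, 2 and 3. At these depths a count of 0 allowed a level of up to 0.0672 to 0.0929 CPM (counts scaled to the library total) per library, from 3 counts and for counting error only. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

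The comparison of heparin with control libraries addressed which hepatocyte transcripts respond to heparin. The albumin gene (Alb) was among the deepest falls, at 403 ± 60.05 CPM in controls and 5.82 ± 0.426 CPM with heparin (SD, n = 3 per group). The largest rise was that of lipocalin 2 (Lcn2), an iron-siderophore binding protein, at 0.658 ± 0.285 CPM in controls and 697 ± 57.3 CPM with heparin. Genes of DNA replication, mitosis and cholesterol synthesis fell nearly as whole groups, as did the FGF receptor genes Fgfr2 and Fgfr3 and the ligand-side genes Fgf1 and Fgfbp1. Of 14061 genes tested, 5705 changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p under 0.05), 2759 higher and 2946 lower with heparin. Without scaling beyond library size the split was 1701 higher and 4496 lower, because that setting moved the median log2 fold change of all genes from -0.04 to -0.21. An absolute log2 fold change of at least 1 was reached by 593 of the higher and 958 of the lower genes. The CPM ranges of the groups did not overlap for 7079 genes, 50.3% of those tested, against 10% by chance for 3 libraries against 3.

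The series title names an axis of FGF receptors, the kinase ERK and HRG, so these genes were examined first. HRG was taken as the mouse gene Hrg, and whether the title refers to its transcript in these cells is not given in the sources used here. Hrg (ENSMUSG00000022877), the mouse gene for histidine-rich glycoprotein, a heparin-binding plasma protein made by the liver, had 1 read in the 6 libraries together, in heparin 2. Fgfr1 (ENSMUSG00000031565) had 2 reads, both in heparin 1. Neither gene was tested, and a difference between the groups was not detectable at this depth. Fgfr2, Fgfr3, Fgfr4 and the co-receptor gene Klb fell. Fgfrl1, a receptor family member without a kinase domain, named after its values were seen, rose (log2 fold change 0.42, edgeR adjusted p = 0.0166). Fgfr2 (ENSMUSG00000030849) went from 58.1 ± 6.78 to 12.3 ± 0.951 CPM, a log2 fold change of -2.25 (SE 0.11) and edgeR adjusted p = 3.81e-08. Fgfr3 (ENSMUSG00000054252) went from 110.1 ± 24.7 to 21.3 ± 1.502 CPM, a log2 fold change of -2.37 (SE 0.15) and edgeR adjusted p = 1.93e-07. Klb (ENSMUSG00000029195), which encodes beta-klotho and serves endocrine FGFs, went from 4.62 ± 0.573 to 0.861 ± 0.179 CPM, with a log2 fold change of -2.43 (SE 0.24) and edgeR adjusted p = 8.05e-06. The decrease was smallest for Fgfr4 (ENSMUSG00000005320), the main FGF receptor of the adult liver, from 43.8 ± 1.85 to 30.5 ± 2.76 CPM, with a log2 fold change of -0.52 (SE 0.10) and edgeR adjusted p = 0.00107. With Hrg, Fgfr1, Fgfr2, Fgfr3, Fgfr4 and Klb taken as the list, the 4 decreases also passed when adjusted over the list alone, with Fgfr4 the highest at adjusted p = 0.000159.

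**Figure D1:**
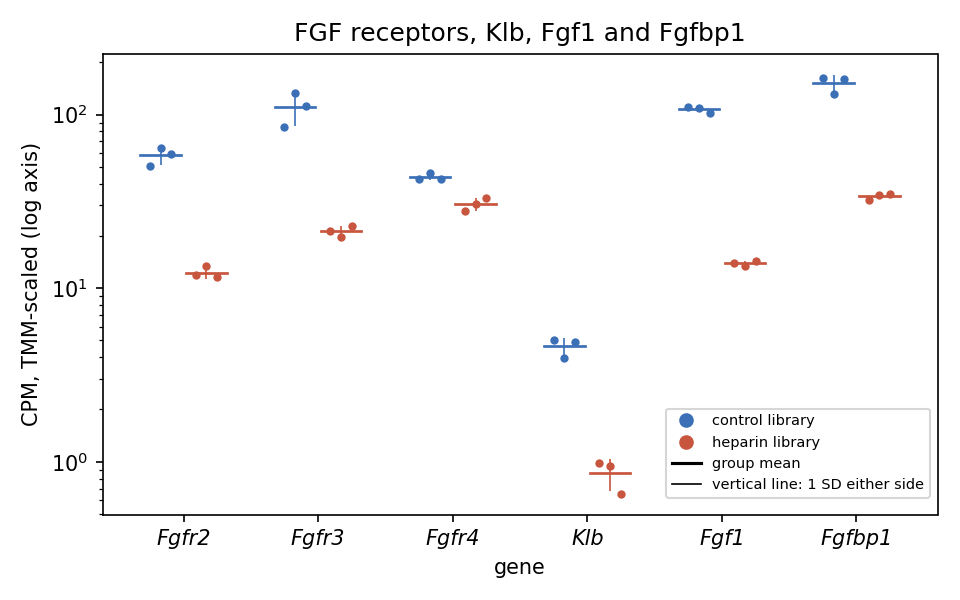
CPM per library on a log axis for 3 FGF receptor genes, Klb, Fgf1 and Fgfbp1, with points for libraries, horizontal lines for group means and vertical lines for 1 SD either side (3 libraries per group). For every gene shown, each heparin library lies under each control library, and Fgfr4 has the narrowest gap (43.8 against 30.5 CPM); Fgfr1 and Hrg, with 2 and 1 reads, are not drawn.

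The list of FGF receptors and proximal signalling had 25 measured members, of which 10 rose and 5 fell, the same numbers when adjusted over the list alone, and 6 rose and 6 fell without scaling. Those that fell were Fgfr2, Fgfr3, Fgfr4, Klb and Flrt3, a membrane protein that binds FGF receptors (19.0 to 3.09 CPM). The risers included the downstream kinase genes Map2k1 and Mapk3, which were named after their values were seen. As a whole the list was not called (camera, higher, adjusted p = 0.385), and its median log2 fold change of 0.15 and mean of -0.23 had opposite signs. The median turned to -0.02 without scaling.

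Among the FGF ligands and binding proteins, 3 of 7 measured members fell and none rose, also when adjusted over the list alone. Fgf1 fell 7.71-fold, from 107.5 ± 4.15 to 13.9 ± 0.410 CPM. Fgfbp1, a carrier that releases FGFs from heparan sulfate, fell 4.47-fold, from 151.8 ± 17.5 to 33.9 ± 1.36 CPM. The third, Fgf13, is an intracellular family member that is not secreted (34.2 to 23.1 CPM). Fgf2 was near the detection limit (0.432 and 0.190 CPM) and did not pass (edgeR adjusted p = 0.132), although it did without heparin 1 (edgeR adjusted p = 0.0408, the lowest of a range up to 0.396 over the settings tried). The ligands were called lower as a list (camera adjusted p = 0.0107), and had adjusted p = 0.343 with an estimated correlation.

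Genes induced by ERK, including its feedback inhibitors, moved both ways. Of 26 measured members, 8 rose and 11 fell, or 9 and 11 when adjusted over the list alone, and 5 and 13 without scaling. The feedback gene Spry1 fell 4.05-fold (18.8 to 4.64 CPM) and the ERK phosphatase gene Dusp6 1.95-fold (202 ± 9.33 to 103 ± 3.80 CPM). The immediate-early gene Egr1 rose 5.90-fold (3.87 ± 0.874 to 22.9 ± 1.82 CPM) and the phosphatase gene Dusp4 rose 2.01-fold (63.4 to 127 CPM). Camera did not call the list (lower, adjusted p = 0.446), and its median log2 fold change of -0.23 and mean of 0.05 differed in sign. The fry test, which asks whether the members move on balance one way, called it lower (adjusted p = 0.0128).

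Coagulation and fibrinolysis genes were examined because the title concerns thrombosis. Of 24 measured members, 7 rose and 12 fell, also when adjusted over the list alone, and 3 rose and 12 fell without scaling. Fibrinogen beta chain (Fgb) fell from 2.67 to 0.204 CPM, Serpina10, which encodes protein Z-dependent protease inhibitor, from 4.15 to 0.845 CPM, and the protease gene Habp2 from 283 ± 39.3 to 156 ± 9.63 CPM. The clotting initiator gene F3 and Tfpi, the gene of its inhibitor, both named after their values were seen, rose with log2 fold changes of 0.36 and 0.35. Other risers moved more, such as F11 at 3.47 (0.242 to 2.63 CPM), also named after its values were seen. The list was not called by camera (adjusted p = 0.119), whereas fry called it lower (adjusted p = 0.000149).

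Genes for heparan sulfate proteoglycans and their synthesis, the cell's own relatives of heparin, were split, with 9 of 31 rising and 8 falling (10 and 8 adjusted over the list alone, 6 and 9 without scaling). The chain-elongating enzyme gene Ext1 rose 3.85-fold (115 ± 9.37 to 443 ± 14.6 CPM). Ugdh, which makes UDP-glucuronate, fell 2.88-fold and the sulfate transporter gene Slc26a2 2.23-fold. This list was not called (camera adjusted p = 0.328). Its median log2 fold change was 0.13, and -0.04 without scaling. In the list of lysosomal heparan sulfate degradation and lysosome genes, 16 of 32 rose and 5 fell, also when adjusted over the list alone. Camera called the list higher (adjusted p = 0.0136), with adjusted p = 0.610 with an estimated correlation, and fry did not (adjusted p = 0.0710). Sqstm1, an autophagy receptor, rose 3.11-fold, and the cholesterol exporter gene Npc1 1.77-fold. The sulfatase genes Arsg (4.48-fold), Ids and Sgsh, which act on heparan sulfate, fell instead, as did Neu1 and Atp6v1h; all but Arsg were named after their values were seen. Without scaling, 10 members rose and 6 fell.

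The largest rises and falls among genes with non-overlapping groups included secreted, junctional and enzyme genes. After Lcn2 (ENSMUSG00000026822, log2 fold change 10.03, SE 0.21, edgeR adjusted p = 1.00e-10), the tight junction gene Cldn4 had a log2 fold change of 7.51 (SE 0.24), from 0.289 to 52.3 CPM. The acute-phase gene Orm1 had 7.003 (SE 0.20), the adhesion receptor gene Adgra1 5.64 (SE 0.16), and Saa3, an acute-phase apolipoprotein, 4.24 (SE 0.19). Cyp21a1, the steroid 21-hydroxylase gene, had 5.36 (SE 0.66) and rested on 11 reads in control 1 and 0 in controls 2 and 3, so its fitted fold depends on that library. The other rises were peroxidasin (Pxdn) at 4.65, the nucleotide receptor gene P2ry6 at 4.55, the tolloid-like protease gene Tll1 at 4.24 and tenascin C (Tnc) at 4.20. Among the falls, Alb (ENSMUSG00000029368) had a log2 fold change of -6.11 (SE 0.14, edgeR adjusted p = 1.53e-10). Transthyretin (Ttr) had -4.98 (SE 0.13), from 280 ± 8.05 to 8.82 ± 1.63 CPM. Sptssb, a subunit of serine palmitoyltransferase, had -6.47 (SE 0.32) and the cholecystokinin receptor gene Cckar -6.15 (SE 0.50), resting on 8 and 6 reads with heparin. Others were Hsd3b2 (-4.88), Keg1 (-4.77), Ugt2b35 (-4.72), Cdkl1 (-4.62) and Ranbp3l (-4.55). Hsd3b2, Ugt2b35, Cyp21a1 and Orm1 belong to families or have near-identical copies, so their counts are uncertain as to which copy the reads came from.

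**Figure D2:**
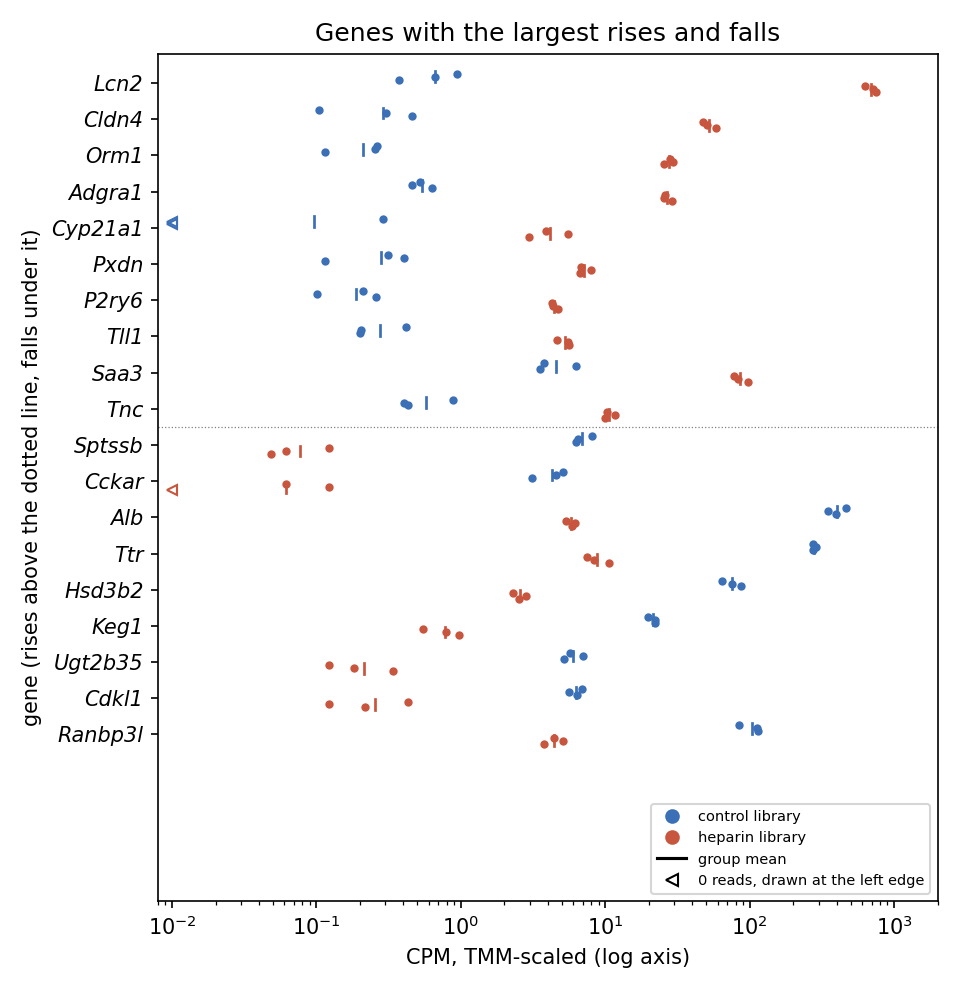
CPM per library on a log axis for 10 genes with the largest rises (top) and 9 of those with the largest falls (bottom), with points for libraries, short lines for group means and open triangles at the left edge for libraries with 0 reads. The 3 libraries of each group lie apart from those of the other for every gene, with Lcn2 at 0.658 CPM on average in controls and 697 CPM with heparin.

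Hepatocyte identity genes were lower as a group: 17 of 24 measured members fell and 3 rose, or 18 and 3 adjusted over the list alone. Besides Alb and Ttr, the alpha-fetoprotein gene Afp fell 3.06-fold (18.0 ± 1.45 to 5.88 ± 0.0737 CPM) and Nr1h4, the bile acid receptor FXR, 2.41-fold (29.9 ± 1.21 to 12.4 ± 0.786 CPM). The risers, named after their values were seen, were Apob and the epithelial keratins Krt8 and Krt18, with log2 fold changes of 1.23, 1.18 and 1.15. The hepatocyte regulator gene Hnf4a, named after its values were seen, did not pass (374 ± 28.0 and 416 ± 32.4 CPM, edgeR adjusted p = 0.236). Camera called hepatocyte identity lower (adjusted p = 0.000562), with adjusted p = 0.343 with an estimated correlation. Bile acid genes were also called lower (camera adjusted p = 0.0375, and adjusted p = 0.343 with an estimated correlation), with 4 of 10 falling and 1 rising, also when adjusted over the list alone, and 6 falling and 1 rising without scaling. Amacr, a side-chain racemase gene, fell 2.76-fold and the canalicular exporter gene Abcc2 2.23-fold. The basolateral exporter gene Abcc3, named after its values were seen, rose. Without control 1 that list was not called (camera adjusted p = 0.0573, the highest of a range from 0.0234 over the settings tried).

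Cholesterol synthesis and uptake genes, targets of SREBP2, fell in 24 of 27 measured members with none rising, also when adjusted over the list alone. Stard4, a sterol carrier, fell 2.91-fold (171 ± 9.94 to 58.9 ± 3.72 CPM) and lanosterol synthase (Lss) 2.66-fold (223 ± 28.5 to 83.8 ± 2.30 CPM). The decrease was called for the list (camera adjusted p = 2.46e-08), with adjusted p = 0.343 with an estimated correlation. Of 18 fatty acid synthesis genes, 6 fell and 1 rose, also when adjusted over the list alone, 10 fell and 1 rose without scaling, and the list was not called (camera adjusted p = 0.202). The elongase gene Elovl6 fell 5.51-fold and Acss2, which makes acetyl-CoA from acetate, 3.75-fold. Targets of PPAR-alpha were split, 6 of 23 rising and 6 falling, also when adjusted over the list alone (camera adjusted p = 0.601). Plin2, a lipid droplet coat protein, rose 2.80-fold (493 ± 26.0 to 1382 ± 102 CPM), and the pantetheinase gene Vnn1 fell by 0.82 on the log2 scale. The median log2 fold change of that list was 0.05, and -0.12 without scaling, where 4 rose and 8 fell.

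In the NF-kB list 20 of 30 rose and 4 fell, or 21 and 4 adjusted over the list alone, and 17 and 6 without scaling. Tnfaip3, an inhibitor of NF-kB, rose 3.31-fold (116 ± 4.72 to 385 ± 14.7 CPM), the receptor gene Tlr2 4.03-fold and the chemokine gene Ccl7 4.06-fold. The chemokine gene Ccl20 fell 17.8-fold (168 ± 31.1 to 9.42 ± 0.889 CPM), and Ptgs2, Cxcl10 and Icam1, named after their values were seen, fell as well. This list was called higher (camera adjusted p = 7.95e-05), with adjusted p = 0.343 with an estimated correlation. The acute phase list had 12 of 25 rising and 6 falling, also when adjusted over the list alone. Besides Lcn2, Orm1 and Saa3, the interleukin 1 receptor antagonist gene Il1rn rose 3.52-fold (15.8 ± 1.38 to 55.6 ± 3.69 CPM). Fgb fell, as did Fga, Apcs, Cp, Mt1 and the STAT3 feedback gene Socs3, which were named after their values were seen. Acute phase genes were called higher (camera adjusted p = 0.0195), with adjusted p = 0.343 with an estimated correlation, and were not called without heparin 3 (camera adjusted p = 0.0562, in a range from 0.00240 over the settings tried). Interferon response genes were not called (camera adjusted p = 0.144), with 9 of 29 rising and 5 falling, or 10 and 5 adjusted over the list alone, and 6 and 7 without scaling. They were called higher without a filter on low counts (camera adjusted p = 0.0326, in a range up to 0.388). The antiviral genes Ifit3b, Ifit3 and Ifit2 fell 15.3-fold, 12.6-fold and 2.90-fold, whereas Stat2 rose 1.502-fold; Ifit3 and Ifit3b are close copies, so their separate values are uncertain. The median of this list, a log2 fold change of 0.15, became -0.02 without scaling.

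In the list of TGF-beta, extracellular matrix and fibrosis genes, 16 of 30 rose and 5 fell, or 17 and 5 adjusted over the list alone. Fibronectin (Fn1) rose 4.40-fold (230 ± 24.8 to 1014 ± 14.1 CPM) and the laminin gene Lamb1 6.80-fold (2.84 to 19.3 CPM). The ligand gene Tgfb3 fell 3.71-fold, and Tgfb2, the receptor gene Tgfbr2, Sparc and Lamc1, named after their values were seen, also fell. Ligand and receptor genes went both ways: Tgfb1 rose 2.30-fold (30.5 to 69.9 CPM) and the receptor gene Tgfbr1 3.15-fold (112 to 353 CPM). Both were also named after their values were seen. Matrix genes were called higher (camera adjusted p = 0.00283), with adjusted p = 0.358 with an estimated correlation. Among YAP-TEAD targets 14 of 22 rose and 3 fell, also when adjusted over the list alone, and 9 rose and 7 fell without scaling. The ecto-nucleotidase gene Nt5e rose 3.67-fold, Ccn2 2.18-fold and Ccn1 2.24-fold; both Ccn genes encode matricellular proteins. YAP-TEAD targets were called higher (camera adjusted p = 0.00648), with adjusted p = 0.343 with an estimated correlation. Of 14 BMP-SMAD genes 5 rose and 4 fell, or 5 and 6 adjusted over the list alone, and 4 and 6 without scaling. The target genes Id2 and Atoh8 fell 8.51-fold (293 ± 28.9 to 34.4 ± 0.982 CPM) and 10.3-fold, while the target gene Smad7 and the receptor gene Acvr1 rose 2.19-fold and 2.39-fold. Camera did not call this list (higher, adjusted p = 0.932), and its median log2 fold change of 0.08 and mean of -0.35 differed in sign; the median became -0.11 without scaling. Wnt-beta-catenin targets were not called either (camera adjusted p = 0.0680), with 5 of 8 falling and 1, Tcf7, rising, also when adjusted over the list alone. Camera called that list in 4 of 14 settings: without control 3, with limma voom, with the length and GC trend taken out and without a filter (adjusted p = 0.0403, 0.0406, 0.0410 and 0.0464, in a range up to 0.105). Fry called it lower (adjusted p = 0.00284). Cyclin D1 (Ccnd1) fell 2.14-fold, and glutamine synthetase (Glul) 1.90-fold.

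Proliferation genes were lower almost throughout. Of 35 DNA replication and G1/S genes 34 fell and none rose, also when adjusted over the list alone. The exception was Fen1, named after its values were seen (2.45 and 1.77 CPM, edgeR adjusted p = 0.171). Thymidine kinase (Tk1) fell 5.07-fold (53.2 ± 7.85 to 10.5 ± 1.53 CPM), the ribonucleotide reductase subunit gene Rrm2 3.67-fold (95.2 ± 10.9 to 26.0 ± 3.13 CPM) and the replication licensing gene Cdc6 9.38-fold. Replication genes were called lower (camera adjusted p = 4.07e-14), with adjusted p = 0.343 with an estimated correlation. Of 34 mitosis and G2/M genes 31 fell and none rose, or 33 adjusted over the list alone. Cdk1 fell 2.45-fold (119 ± 11.2 to 48.6 ± 1.34 CPM), Aurkb 2.30-fold and cyclin A2 (Ccna2) 2.16-fold. This list was called lower too (camera adjusted p = 1.67e-09), with adjusted p = 0.343 with an estimated correlation. Targets of p53 were not called (camera adjusted p = 0.1504), with 4 of 28 rising and 11 falling, or 4 and 12 adjusted over the list alone and 3 and 15 without scaling, whereas fry called them lower (adjusted p = 9.34e-05). The cell cycle inhibitor gene Cdkn1a, named after its values were seen, did not pass (224 ± 6.42 and 262 ± 39.8 CPM, edgeR adjusted p = 0.119), and the stress cytokine gene Gdf15 fell 2.29-fold.

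Among NRF2 antioxidant genes 12 of 29 fell, also when adjusted over the list alone, and 18 without scaling, including Gclc, a subunit of the first enzyme of glutathione synthesis, 3.39-fold (309 ± 21.7 to 91.0 ± 7.66 CPM), and Gsta3 2.56-fold. Heme oxygenase 1 (Hmox1) was the 1 riser, 4.75-fold (61.3 ± 13.9 to 291 ± 51.2 CPM). NRF2 genes were called lower (camera adjusted p = 0.00648), with adjusted p = 0.481 with an estimated correlation. Hypoxia and glycolysis genes were called higher (camera adjusted p = 0.00399, and adjusted p = 0.448 with an estimated correlation). Of 32 members 14 rose and 1 fell, also when adjusted over the list alone, and 9 rose and 5 fell without scaling. The member that fell was Gapdh, named after its values were seen. Hexokinase 2 (Hk2) rose 14.3-fold (1.22 ± 0.119 to 17.5 ± 0.350 CPM), the glucose transporter gene Slc2a1 2.65-fold and Pfkfb3, a regulator of glycolysis, 2.49-fold. Nuclear genes of oxidative phosphorylation fell in 19 of 45 members with none rising, or 21 adjusted over the list alone and 35 without scaling. Cytochrome c (Cycs) fell 1.40-fold and Ndufa5 1.58-fold. That list was called lower (camera adjusted p = 0.00511), with adjusted p = 0.590 with an estimated correlation, and was not called once the length and GC trend was taken out (camera adjusted p = 0.0626, in a range from 0.000282). Endoplasmic reticulum chaperone genes fell in 11 of 25 and rose in 3, also when adjusted over the list alone, with 18 falling and none rising without scaling. Creld2 fell 1.75-fold and Manf 1.59-fold. The call lay at the threshold (camera adjusted p = 0.0498, and adjusted p = 0.590 with an estimated correlation), and held in 6 of 14 settings tried (0.0199 to 0.202). It was lost without control 1, heparin 1, heparin 2 or heparin 3 (camera adjusted p = 0.202, 0.0994, 0.0769 and 0.0602). It was also lost with RLE size factors, without a filter, with the replicate block and without mitochondrial transcripts (camera adjusted p = 0.0561, 0.0643, 0.0721 and 0.0516). ATF4 genes were not called (camera adjusted p = 0.790), 9 of 33 rising and 10 falling, or 10 and 10 adjusted over the list alone, and 7 and 15 without scaling. The transsulfuration genes Cbs and Cth fell 6.15-fold and 2.92-fold, and the stress transcription factor gene Atf3 rose 2.27-fold.

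**Figure D3:**
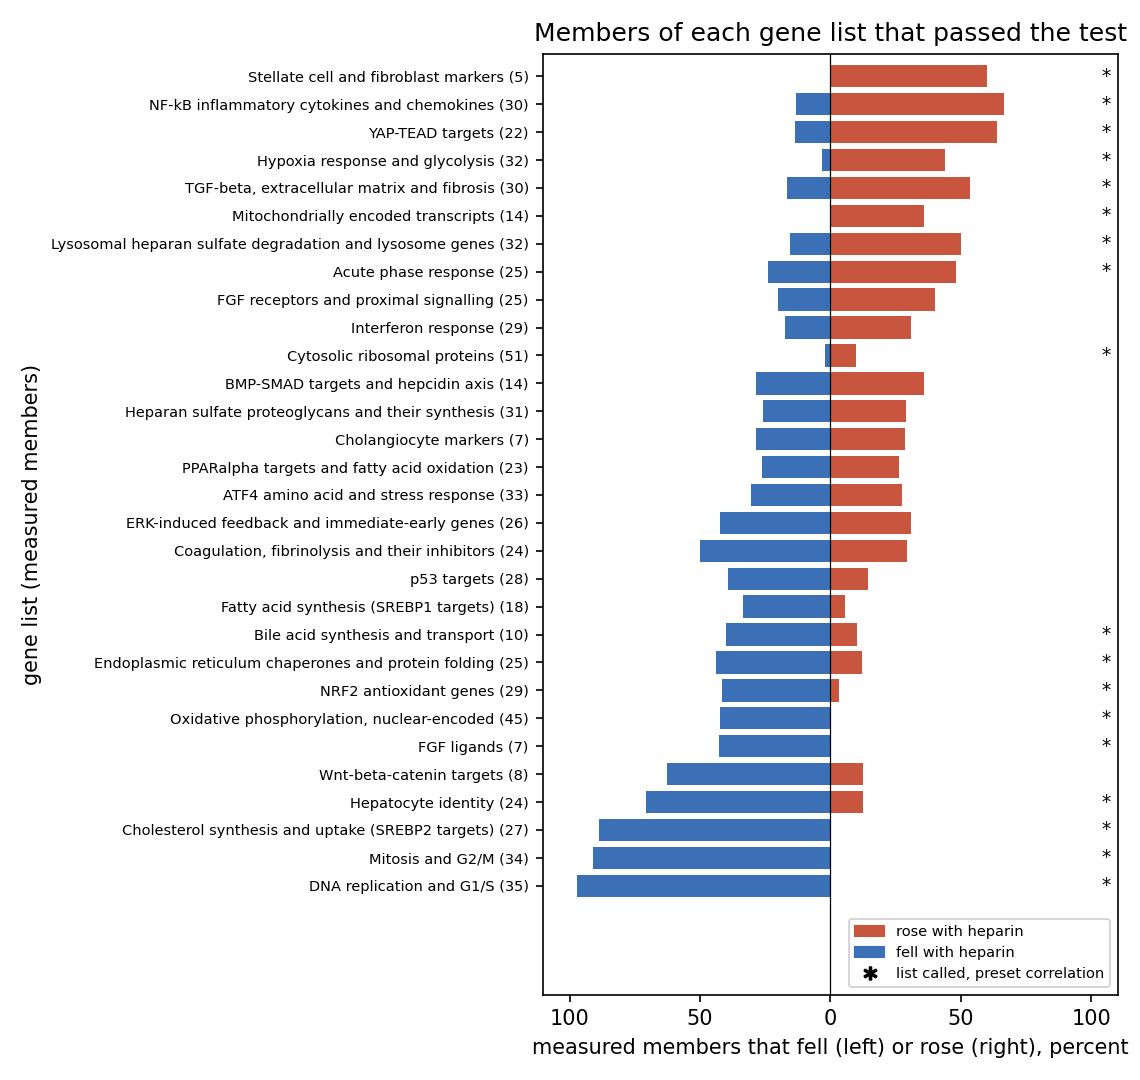
Percent of each list's measured members that fell (left) or rose (right) with heparin by edgeR's test, for the 30 lists tested, with the number of measured members after each name; a star marks lists called by camera with a preset correlation. DNA replication (34 of 35) and mitosis (31 of 34) have the longest bars to the left, and the NF-kB list (20 of 30) the longest to the right; no list was called with an estimated correlation, and 35 oxidative phosphorylation genes fell without scaling.

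Markers of other cell types were present at low levels for the most part. Of 15 stellate cell and fibroblast markers 5 were measured, and 3 rose, also when adjusted over the list alone. Pdgfrb, in controls at about the level that a count of 0 allows, went from 0.0683 ± 0.0775 to 2.72 ± 0.537 CPM, Col1a1 from 1.03 ± 0.344 to 4.46 ± 0.643 CPM and Pdgfra from 0.0878 to 0.602 CPM. Both collagen members are also in the matrix list, with which these markers moved. These markers were called higher (camera adjusted p = 0.0251), with adjusted p = 0.343 with an estimated correlation, but not once the length and GC trend was taken out (camera adjusted p = 0.0626, in a range from 0.00520). Col1a2 did not pass (0.322 ± 0.536 and 0.782 ± 0.811 CPM). It did without control 1 and without a filter on low counts (edgeR adjusted p = 0.00413 and 0.0302, in a range up to 0.990 over the settings tried). Endothelial and macrophage lists had 4 measured members each and were not tested as lists. The endothelial markers Stab1 (2.96 to 12.5 CPM) and Cdh5 (0.281 to 1.12 CPM) rose, and of the macrophage markers Csf1r fell (24.5 to 7.27 CPM). Of 7 cholangiocyte markers, Krt7 and Sox9 rose 1.62-fold and 1.51-fold, while Aqp1 and Krt19 fell 14.99-fold and 1.503-fold, the same counts when adjusted over the list alone, and the list was not called (camera adjusted p = 0.790).

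Mitochondrial transcripts, often read as a sign of RNA or cell quality, took 4.81, 2.24 and 2.67% of counts in controls 1, 2 and 3, and 5.47, 4.89 and 3.79% in heparin 1, 2 and 3. The difference between the group means, 3.24 ± 1.38% and 4.71 ± 0.854%, did not pass a two-sided exact permutation test (p = 0.20), which with 3 against 3 cannot go under 0.10. The mitochondrial list was called higher (camera adjusted p = 0.00869), with adjusted p = 0.590 with an estimated correlation; 5 of 14 members rose, or 8 adjusted over the list alone, and 2 without scaling. Fry did not call that list (adjusted p = 0.153). The risers mt-Rnr1, mt-Atp6, mt-Co3 and mt-Co1 did not pass with DESeq2 (adjusted p = 0.1545, 0.131, 0.1697 and 0.1425). The call for mt-Co1 (fitted log2 fold change 0.60, SE 0.21) was also lost without scaling (edgeR adjusted p = 0.0796), and without control 2, control 3, heparin 1 or heparin 2 (edgeR adjusted p = 0.134, 0.161, 0.132 and 0.0953, in a range from 2.39e-06). The calls for mt-Rnr1, mt-Atp6 and mt-Co3 were lost without control 2 (edgeR adjusted p = 0.0784, 0.0766 and 0.0756) or control 3 (0.102, 0.103 and 0.1145), in ranges from 6.58e-15, 4.92e-41 and 1.47e-11 over the settings tried. Without heparin 1 mt-Rnr1 did not pass (0.06885), without heparin 3 mt-Atp6 and mt-Co3 did not (0.186 and 0.13), and mt-Co3 did not without heparin 2 or without scaling (0.0866 and 0.0648). Ribosomal protein genes were called higher (camera adjusted p = 0.0195), with adjusted p = 0.681 with an estimated correlation, but 5 of 51 rose, 1 fell and 0 passed when adjusted over the list alone, while at an unadjusted edgeR p under 0.05 there were 10 higher and 1 lower; without scaling 1 rose and 2 fell. Their median log2 fold change of 0.15 became -0.03 without scaling, and the list was not called without scaling, control 2 or heparin 3 (camera adjusted p = 0.277, 0.0783 and 0.132, in a range from 0.00190). Mitochondrial and ribosomal protein genes have many copies in the genome, so their values are uncertain.

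Across the 30 lists tested, camera with a preset correlation called 18, 9 higher and 9 lower. With the correlation estimated from the libraries it called 0, the lowest adjusted p being 0.343, and 1 list had an unadjusted p under 0.05; fry called 20. Control 1 stood apart from the other controls on the second principal component, and without it 7291 genes changed.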

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

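The settings that removed the length and GC trend and the mitochondrial transcripts were chosen after the data were seen. Over the settings that changed the scaling, filter or tool, or added the replicate block, the number of changed genes ranged from 4685 to 6197, against 5705. It was 6243 with the length and GC trend taken out and 5713 without mitochondrial transcripts. With an absolute log2 fold change of at least 1 it was 1551, with 593 higher and 958 lower, since that setting keeps a subset. Without scaling beyond library size, 1701 genes were higher and 4496 lower, and the median of all genes moved to -0.21. DESeq2 called 5572 genes, 5253 of them shared with edgeR. No gene called in both the edgeR test with TMM and an alternative had the opposite direction there. Leaving out 1 library gave 4135 to 7291 changed genes, 2006 to 3682 higher and 2129 to 3609 lower, with the lowest counts without control 3 and the highest without control 1, and 15 to 19 called lists. Fgfr2, Fgfr3, Fgfr4 and Klb, a count of 4, passed with each of these scalings, filters, tools and left-out libraries and with the block; the fold minimum was applied to the counts of all genes, and Fgfr4 (-0.52) lies under it. Of 142 genes followed, 132 kept their side of the threshold in every setting that gave an adjusted p, and none that passed reversed. The 10 exceptions were Fgf2, Col1a2, and mitochondrial and ribosomal protein genes. The genes followed came from the naming rule, which took most of them for large changes or small p in these data, so most were likely to stay. Over all 5705 called genes, the share called again ran from 71.3% without control 3 to 99.8% without mitochondrial transcripts. It was 73.3% without heparin 2 and 76.0% without control 2. The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.186, 0.039 and -0.121, and control 1 correlated best with heparin 3 (0.217). With the replicate block 4685 genes changed, 2302 higher and 2383 lower, and 17 lists were called, against 18, without the endoplasmic reticulum chaperones (camera adjusted p = 0.0721). With an estimated correlation 0 lists were called (lowest camera adjusted p = 0.343). Among the called lists the estimates lay above the preset 0.01 in all but the FGF ligands (-0.139), from 0.0456 for bile acid genes to 0.831 for mitochondrial transcripts. A higher correlation raises camera's p. With an estimated correlation camera also uses the few degrees of freedom that 6 libraries leave, which raises p as well. The lost calls are therefore not due to correlation alone, and the share of each was not separated. For the FGF ligands, whose estimate lay under the preset value, unadjusted camera p went from 0.00428 to 0.0423. A higher correlation does not account for that rise. All of these calls rest on the preset setting. Fry called 20, and turned the BMP-SMAD list to lower (adjusted p = 0.00764, from 0.689 to 0.991 over the other camera settings); the cause was not tested. Taking out the length and GC trend ended the calls for oxidative phosphorylation and for stellate cell markers (camera adjusted p = 0.0626 for both, with lows of 0.000282 and 0.00520 over the settings); the cause was not tested. Hrg and Fgfr1, with 1 and 2 reads in all, were close to absent in these libraries. Both lay under the level that a count of 0 allows (0.0672 to 0.0929 CPM), so a difference between the groups could not be assessed.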

Other observations

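Chosen after the result was seen were the gene families, the removal of the length and GC trend, and the tests of dilution by another cell type and of heparin RNA in control 1. Families of genes sharing a symbol stem were tested, 134 families with at least 10 measured members each, by camera with the preset correlation. Intracellular serpins of the Serpinb family were higher (adjusted p = 0.00161), 8 of 11 members rising and none falling. Serpinb9b was at 52.6 ± 6.65 CPM in controls and 167 ± 5.42 CPM with heparin, and Serpinb6b at 159 ± 7.24 and 230 ± 19.5 CPM. The risers Serpinb9e, Serpinb9g, Serpinb9f and Serpinb9c stayed low also with heparin (0.472, 0.392, 0.391 and 0.757 CPM). The count of risers and the family call therefore rest partly on low values. Cytochrome P450 genes, many of them drug- and steroid-metabolising enzymes, were lower (adjusted p = 0.00217), 20 of 36 falling and 2 rising, Cyp21a1 and Cyp11a1. Cyp2c68 went from 222 ± 10.8 to 95.7 ± 7.82 CPM, Cyp3a13 from 55.0 ± 3.79 to 18.5 ± 0.726 CPM and Cyp1a1 from 6.33 ± 0.290 to 0.616 ± 0.295 CPM. Aldo-keto reductase genes were lower as well (adjusted p = 0.00818), 8 of 12 falling and none rising, with Akr1c19 12.002-fold and Akr1c14 8.47-fold lower. None of these families was called with an estimated correlation (adjusted p = 0.739 with an estimated correlation for all 3), and their members share sequence, so single values are uncertain.

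Genes of the Stk stem, most of them kinase genes, were higher (camera adjusted p = 0.0219), with 8 of 16 rising and none falling. Stk17b led, at 18.8 ± 1.68 CPM in controls and 105 ± 7.31 CPM with heparin. The risers included Stk11ip, which is not a kinase gene, and the stem took in the pseudogene Stk19-ps1. Genes of the Zbtb stem, mostly transcription factor genes (camera adjusted p = 0.0270), had 17 of 39 rising and 2 falling, or 11 and 2 without scaling. Zbtb38 was 2.50-fold higher. Genes of the Eif stem, mostly translation initiation factor genes (camera adjusted p = 0.0301), had 20 of 54 rising and 3 falling. Without scaling beyond library size 7 rose and 9 fell. The risers included the kinase gene Eif2ak3 and the binding protein genes Eif4ebp1 and Eif4ebp2, and the stem took in pseudogenes. Mcm genes, most of which are also in the DNA replication list, had 8 of 10 falling and none rising (adjusted p = 0.00818). With an estimated correlation the adjusted p of these 4 families lay between 0.739 and 0.790.

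The first pattern is the breadth of the difference, 5705 changed genes. The 9 other splits of the 6 libraries into 3 and 3 gave at most 0 called genes, and 1 split, the real one, gave 5705. A share under 0.05 cannot be reached with 10 splits. Each other split also put control and heparin libraries on the same side, where a difference between the groups adds to the spread. The splits therefore do not show how many genes would be called without such a difference. A difference in the copy number of whole chromosomes between the cultures is argued against. Chromosome medians lay between -0.10 and 0.07 of the median of all genes on the log2 scale. Taking each chromosome's median out left 99.9% of the number of genes with an absolute log2 fold change of at least 1. Medians this small could hardly have changed that number, so it adds little. Copy-number changes of parts of chromosomes were not tested. A length or GC bias is argued against as the whole cause, because after that trend was taken out the number of called genes was 109% of that before, and 5153 of the 5705 genes (90.3%) were called again. Heparin itself stays open as a biological hypothesis, as does any difference in passage, density, medium or day between the cultures, which the labels do not give.

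The second pattern is the loss of Alb and Ttr transcripts while Hnf4a (log2 fold change 0.15, SE 0.10) did not pass the test. Dilution of the hepatocytes by cells without Hnf4a, Krt8 and Krt18 transcripts would lower these along with Alb and is argued against. The lowest log2 fold change among them was 0.15 (Hnf4a, SE 0.10), against -6.11 for Alb. Dilution by epithelial or hepatocyte-like cells that express these genes would not lower them and was not tested. Weaker glucocorticoid signalling may contribute and stays open: Tsc22d3 fell (log2 fold change -0.86, SE 0.12), Fkbp5 did not pass (-0.25, SE 0.10, edgeR adjusted p = 0.0636), and Klf9 and Sgk1, also induced by glucocorticoids, rose (0.65 and 0.78). Per1 did not pass (0.01, SE 0.13, edgeR adjusted p = 0.939), and Zbtb16, too low to test, was at 0.168 ± 0.0364 CPM in controls and had 0 reads with heparin. Whether the 2 groups were given the same hormone supplements is not given in the sources used here.

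The third pattern is control 1, which lay toward the heparin libraries on the first principal component by 15.6% of the distance from controls 2 and 3, and had a mitochondrial share of 4.81% against 2.24 and 2.67%. Heparin RNA mixed into control 1 is argued against, because Lcn2, Cldn4 and Orm1 allow at most 0.280% of such RNA. A length or GC bias is argued against as the whole cause, since taking out the trend lowered the root mean square deviation of control 1 from the other controls by 3.21%. A difference in culture state or RNA quality of that sample stays open, and no biological explanation was tested.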
